A study of Homo sapiens with 2 samples.

How the data were processed

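Total RNA of human trophoblast cultures was profiled on Affymetrix Human Genome U133 Plus 2.0 arrays, on which each transcript is read by a probe set of short oligonucleotides placed mostly near its 3 prime end. Per the labels, 1 array was hybridised with RNA labelled 6 h and 1 array with RNA labelled 118 h. The labels give no donor, isolation method, medium or replicate, and the time of 118 h is used as the label gives it. The deposited values are probe set intensities on a linear scale, 1 column per array, and the submitters' processing notes name MAS5 as the program that made them, with no version. The 2% trimmed mean of the deposited intensities was 500.06 on each array, so the authors' values carry MAS5's global scaling to a target of 500. They ran from 0.1 to 43197.2 at 6 h and from 0.2 to 37522.0 at 118 h. Per the series' design text, the submitters kept genes significantly above background that changed by more than 2-fold. Detection p-values were not used here, and a floor on the signal took their place.

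The table held 54675 probe sets. A platform annotation paired 42898 of them with genes, of which 41097 had 1 gene symbol and 1801 had several. The other 11777 probe sets stayed unnamed. Symbols were updated through the Entrez gene identifier to those of a RefSeq gene table of assembly GRCh38.p14, which matched for 41043 probe sets. Probe sets of several genes were not named, so the beta subunits of chorionic gonadotropin and CSH2 are not reported. Other list members with no uniquely named probe set were not analysed here. Genes of the Y chromosome and XIST were left out. No coordinates are given because the files name no genome build.

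Each array was rescaled to a 2% trimmed mean of 500, with factors of 0.99988 and 0.99989. The floor was the higher of the arrays' medians over probe sets other than controls, 143.68, and lower signals were raised to it. Over probe sets other than controls the deposited columns had medians of 143.7 at 6 h and 123.9 at 118 h. At 6 h 50.0% of the probe sets and at 118 h 46.4% reached the floor. A gene was measured if it reached the floor on at least 1 array, and its probe set with the highest mean log2 signal stood for it. Ratios are 118 h over 6 h. Where 1 side lay below the floor, the fold is a bound and is written "at least". Genes were called higher or lower at a ratio of at least 2 or at most 0.5. With 1 array per time no test between times is possible, and no p-value is given. The number of arrays limits the precision.

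For 29 gene lists the median log2 ratio of the measured members was set against 10000 random lists of the same size, matched on mean signal in 20 bins. A list outside percentiles 2.5 to 97.5 is said to stand apart. This describes these 2 arrays and is not a test of the times. The lists, the 2-fold rule, the floor, the alternatives and the rule for named genes were fixed before the data were examined. The rule named the 12 highest and 12 lowest genes above the floor on both arrays, the 6 largest bounds in each direction, and up to 5 members of each list with the largest ratios. It also named any member of the placental hormone, trophoblast fusion and steroid hormone lists, and the control probe sets of GAPDH and ACTB. Genes whose probe sets moved 2-fold in opposite directions were to be named as uncertain. CCL2, CYCS, FOS, HLA-G, JUND, PECAM1, PSG11, RFC4 and RRM1 lie outside the rule and were chosen after their values were seen.

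The precision was described in other ways. Over the 4651 genes with at least 2 probe sets above the floor on both arrays, the robust SD of a log2 ratio, from the difference between the 2 brightest probe sets, was 0.396, and the plain SD was 0.574. The 18 probe sets of the hybridisation controls, which are added after labelling, had a median log2 ratio of -0.07 and an SD of 0.137. The steps were tested on simulated data in which 200 genes were changed by known amounts. With a spread of 0.396 among 13021 simulated genes, 86.6% of the genes changed 2.83-fold and 100.0% of those changed 4-fold were called. Of the unchanged genes 0.96% were called. With a spread of 0.844, these shares were 71.6%, 92.5% and 19.65% among 13556 genes. The spread of 0.844 is the robust SD of the log2 ratios of the 10902 genes above the floor on both arrays. The spread of 0.396 lies between probe sets on the same 2 arrays and holds no variation between cultures or labellings. The plain SD of 0.574 was not simulated. Neither simulation therefore gives the share of false calls between the times. Of 200 lists of 20 unchanged genes, 5.5% stood apart with the smaller spread and 3.5% with the larger. These shares follow from the percentile rule, because the lists were themselves random draws with independent noise. They do not tell how often lists of genes that vary together or share sequence would stand apart.

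The alternatives were no rescaling, equal medians of bright probe sets, quantile normalization, loess centring, floors at the 35th and 70th percentiles, no floor, 50 added before log2, the median over a gene's probe sets, and leaving out probe sets that end in _x_at or _s_at, which can bind related transcripts. For the counts, a 3-fold threshold and agreement of all probe sets were added. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.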

Results

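Gene expression in human trophoblast cultures was measured at 6 h and at 118 h, with 1 microarray per time. Trophoblasts are the epithelial cells of the placenta. Isolated villous cytotrophoblasts are known to fuse in culture into syncytiotrophoblast, the multinucleate layer that makes the hormones of pregnancy. The labels do not say which trophoblast population was plated. The comparison of the 2 times asks which transcripts differ between early and late culture. No value below has a replicate, so no difference can be set against the spread between cultures.

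At 118 h, transcripts of placental hormones, pregnancy-specific glycoproteins and steroid-producing enzymes were higher than at 6 h. PSG1, KISS1 and PSG2 had the largest ratios among the members of these lists. Inflammatory, interferon-stimulated, immediate early and cell cycle genes were lower, among them IL1B, RSAD2, FOSL1 and TYMS. Of 19732 named genes, 13544 reached the signal floor on at least 1 array and 10902 on both. At 118 h, 2177 genes (16.07%) were at least 2-fold higher and 1282 (9.47%) at least 2-fold lower than at 6 h. Of these, 376 of the higher and 256 of the lower genes lay below the floor on 1 array, so their folds are bounds. Folds are those of a gene's brightest probe set. Of the 1169 higher genes with at least 2 measured probe sets 391 were 2-fold higher by all of them, and of 723 such lower genes 254 were 2-fold lower by all. At least 8-fold differences were seen for 95 higher and 69 lower genes. Across the 10902 genes above the floor on both arrays, the log2 signals of the arrays had a Pearson correlation of 0.829, which is across genes and not across independent replicates. The median log2 ratio of these genes was 0.10. Scaling the arrays to equal medians of bright probe sets took it to -0.02 and gave 1766 higher and 1560 lower genes.

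**Figure D1:**
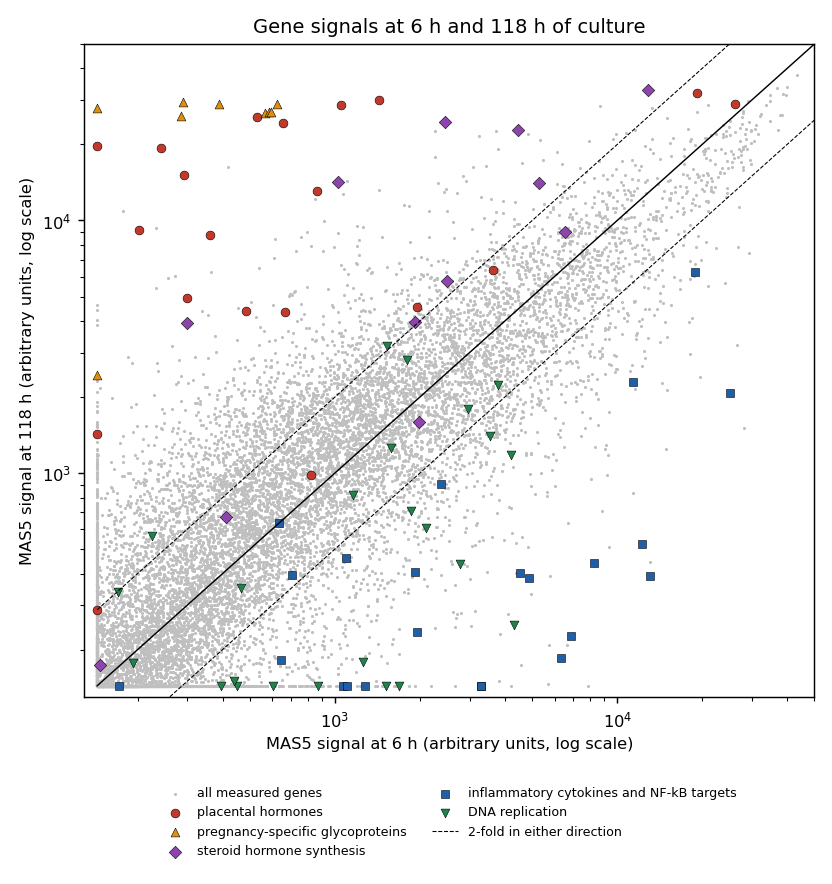
Signal of each measured gene at 6 h (x axis) and 118 h (y axis), in arbitrary MAS5 units on log axes, with signals under the floor of 143.68 drawn at the floor. Grey points are all 13544 measured genes, coloured symbols are members of 5 gene lists, the solid line marks equal signals and the dashed lines 2-fold differences. All 9 measured pregnancy-specific glycoproteins lie above the upper dashed line, and 20 of the 23 inflammatory genes lie below the lower one.

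The genes with the highest ratios included several placental products. KISS1, which encodes the placental peptide kisspeptin, had a signal of 42.9 at 6 h and 19723 at 118 h, at least 137-fold higher. PLAC1, a placenta-specific gene, was 80.1-fold higher, EBI3, a subunit of interleukins 27 and 35, 61.5-fold, and PLAC4 51.8-fold. LGALS14, a placental galectin, was 48.4-fold higher and PAPPA, the protease that cleaves IGF-binding proteins, 45.5-fold. The 8 probe sets of PAPPA ranged in log2 ratio from 1.32 to 6.34. Among genes below the floor at 6 h, the noradrenaline transporter SLC6A2 was at least 32.3-fold higher. MFAP3L was at least 30.9-fold and SYNPO, an actin-associated protein, at least 28.1-fold higher. For SLC6A2, MFAP3L and SYNPO the gene's probe set with the lowest log2 ratio stood at -0.07, 0.39 and 0.17, and SYNPO and MFAP3L were not 2-fold higher by the median of their probe sets.

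Placental hormones and secreted placental proteins were higher as a group. Of 20 measured members 15 were at least 2-fold higher and 0 were 2-fold lower, and the median log2 ratio was 3.98, above the medians of all 10000 random lists. Placental lactogen CSH1 went from 1051 to 28646, 27.3-fold higher, and inhibin alpha (INHA) from 362 to 8778, 24.3-fold higher. Inhibin beta A (INHBA) was 2.32-fold and follistatin-like 3 (FSTL3) 6.51-fold higher. The galectin LGALS13 was 15.2-fold higher, PAPPA2 9.05-fold, and corticotropin-releasing hormone (CRH) at least 9.92-fold. The growth hormone genes GH1 and GH2 were 37.0-fold and 16.5-fold higher and CSHL1 21.0-fold. The probe set of PAPPA2 with the lowest log2 ratio stood at 0.39. CSH1, CSHL1, GH1 and GH2 are near-identical in sequence, so their probe sets cannot be taken as separate genes. Chorionic gonadotropin alpha (CGA) was already at 26215 at 6 h and stood at 29030 at 118 h. TAC3, GDF15 and INSL4 had ratios of 1.19, 1.66 and 1.77, short of 2-fold, and GDF15 was 2-fold higher with loess centring (log2 ratio 1.08) but had a log2 ratio of -0.45 by its other probe set. Leptin (LEP) went from 10.6 to 285.9, and its bound against the floor was 1.99-fold. LEP passed 2-fold with quantile normalization (1.13), loess centring (1.03) and the floor at the 35th percentile (1.93), and without a floor.

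All 9 measured pregnancy-specific glycoproteins, secreted immunoglobulin-like proteins of the syncytiotrophoblast, were higher, with a median log2 ratio of 5.57, above all 10000 random lists. PSG1 was at least 194-fold, PSG2 101-fold, PSG3 91.8-fold and PSG5 74.5-fold higher. PSG6, PSG4, PSG7 and PSG9 were between 45.1-fold and 47.4-fold higher, and PSG11 was at least 17.1-fold higher. Other probe sets gave other values, with lowest log2 ratios of 5.17 for PSG1, 2.97 for PSG5 and 3.79 for PSG9, and a range from 3.37 to 6.61 for PSG6. The 8 genes other than PSG11 stood between 26029 and 29461 at 118 h, so the order of their folds rests mostly on the 6 h signals. Whether signals this bright still follow transcript amount was not tested. The family is close in sequence, so the members cannot be taken as separate genes. Without probe sets ending in _x_at or _s_at, which can bind related transcripts, fewer than 3 members were left and the list had no value.

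Genes of steroid hormone synthesis were also higher, 8 of 12 by at least 2-fold and 0 lower, with a median log2 ratio of 1.29, above all 10000 random lists. CYP11A1, the side-chain cleavage enzyme that makes pregnenolone from cholesterol, was 13.9-fold higher. HSD3B1, which makes progesterone, went from 2448 to 24486, 10.0-fold higher. Aromatase (CYP19A1) was 5.10-fold higher, steroid sulfatase (STS) 2.67-fold and HSD17B1 2.56-fold. The probe set of CYP19A1 with the lowest log2 ratio stood at 0.37 and that of HSD17B1 at 0.78. HSD11B2, which inactivates cortisol, was 13.1-fold higher. The orphan receptor ESRRG was 2.32-fold and the electron donor POR 2.05-fold higher. With equal medians of bright probe sets POR had a log2 ratio of 0.89, and by the median of its probe sets ESRRG had 0.91, both short of 2-fold. FDX1, STARD3 and SULT2B1 had ratios of 1.39, 1.62 and 1.19, and HSD17B12 was 1.25-fold lower. Cholesterol synthesis and uptake did not stand apart, with a median log2 ratio of -0.26 at percentile 4.74. In that list SQLE was 4.10-fold and INSIG1 2.18-fold lower, and LSS 2.80-fold and PMVK 2.17-fold higher. PMVK fell short of 2-fold with every other scaling that moved values, and INSIG1 was not 2-fold lower by the median of its probe sets (-0.85). The probe set that differed least had a log2 ratio of -0.39 for SQLE and 0.58 for LSS.

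The trophoblast fusion list was mixed, with 8 of 21 members higher, 3 lower and a median log2 ratio of 0.23 at percentile 79.96. ERVFRD-1 (syncytin 2), an envelope protein that drives cell fusion, had a signal of 7862 at 6 h and 13.8 at 118 h, at least 54.7-fold lower, the largest bound in that direction. ERVFRD-1 had 1 measured probe set. Its receptor MFSD2A was 14.4-fold higher. ERVW-1 (syncytin 1) went from 10437 to 17150, a ratio of 1.64, and its receptors SLC1A5 and SLC1A4 had log2 ratios of -0.90 and -0.23. SLC1A5 was 2-fold lower with equal medians of bright probe sets (-1.04). The metalloprotease ADAM12 was 38.9-fold and syndecan 1 (SDC1) 4.55-fold higher, with ADAM12 probe sets from 1.67 to 6.81 in log2 ratio. Among transcription factors, DLX4 was 5.34-fold higher, RXRA 3.44-fold, GATA2 2.21-fold, PPARG 2.19-fold and GCM1, an activator of syncytin genes, 2.10-fold. GCM1 and PPARG had log2 ratios of 0.92 and 0.99 with equal medians of bright probe sets, and RXRA and GATA2 of 0.88 and 0.30 by the median of their probe sets, all short of 2-fold. DLX4's other probe set had a log2 ratio of 0.70. OVOL1 was 4.21-fold and the gap junction gene GJA1 5.54-fold lower. DYSF, DLX3, TFAP2A, GATA3, ANXA5, ERVV-1 and ERVMER34-1 differed by less than 2-fold, with log2 ratios from -0.66 to 0.75. ERVMER34-1, at 0.01, turned negative with each other scaling that moved values, and GATA3, at -0.39, turned to 0.10 without probe sets ending in _x_at or _s_at.

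**Figure D2:**
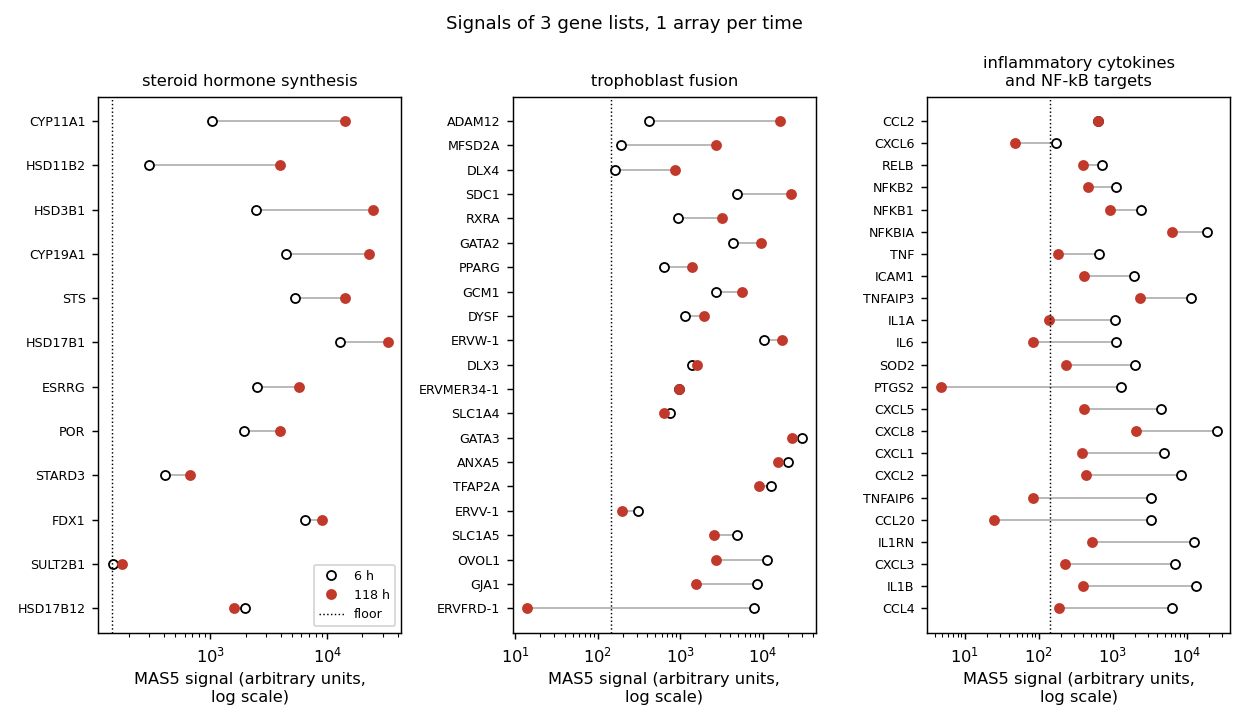
Signals at 6 h (open circles) and 118 h (filled circles) of the measured members of 3 gene lists, in arbitrary MAS5 units on log axes, with 1 array per time and the floor dotted. ERVFRD-1 stands at 7862 and 13.8 while CYP11A1 goes from 1021 to 14234.

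Markers of villous cytotrophoblast did not stand apart as a list, with 6 of 18 members lower, 1 higher and a median log2 ratio of -0.26 at percentile 21.28. PAGE4 was 8.27-fold lower, BCAM 4.97-fold, the imprinted gene PEG10 4.46-fold and integrin ITGA6 3.10-fold. LIFR was the member that was higher, by 6.09-fold, with 0.35 as the lowest log2 ratio of its probe sets. Extravillous trophoblast markers stood apart upward, with 10 of 21 higher, 4 lower and a median log2 ratio of 0.95 at percentile 99.99. HPGD, which degrades prostaglandins, was 11.3-fold higher, HTRA4 10.4-fold and HTRA1 5.05-fold, and DIO2 was at least 4.57-fold higher. The urokinase receptor PLAUR was 9.38-fold lower. DIO2 was not 2-fold higher with other floors or by the median of its probe sets (0.94), nor was PLAUR 2-fold lower without probe sets ending in _x_at or _s_at (-0.79). HLA-G, the antigen by which invasive trophoblast is usually recognised, went from 10838 to 4303, a log2 ratio of -1.33, by a probe set that can bind related transcripts, and its 4 probe sets ranged from -1.33 to -0.34.

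Proliferation genes were lower at 118 h. In the DNA replication list 14 of 24 members were lower and 2 higher, with a median log2 ratio of -1.42 at percentile 0.0. Thymidylate synthase (TYMS) was 17.2-fold lower, CDC6 7.05-fold and MCM5 6.35-fold, while UHRF1 and RRM2 were at least 11.7-fold and 10.6-fold lower. RFC4 and RRM1 were the 2 higher members, with log2 ratios of 1.32 and 1.06, and another probe set of RRM1 had 0.31. In the mitosis list 14 of 28 members were lower and 0 higher, with a median of -1.05 at percentile 0.0. CCNB2 was 6.75-fold, PRC1 5.94-fold and NUSAP1 4.92-fold lower, and CDK1 and KIF2C at least 6.68-fold and 6.27-fold. The other probe set had log2 ratios of -0.55 for CCNB2, -1.19 for NUSAP1 and -0.98 for KIF2C.

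The lowest genes at 118 h included inflammatory mediators. In the list of cytokines and NF-kB targets 20 of 23 members were lower and 0 higher, with a median log2 ratio of -3.07 at percentile 0.0. CCL4 went from 6305 to 185.6, a log2 ratio of -5.09, IL1B was 33.3-fold lower, CXCL3 30.3-fold and the interleukin 1 antagonist IL1RN 23.5-fold. CCL20 and TNFAIP6 were at least 23.0-fold and 22.9-fold lower. CCL2 differed little, at 632 and 633. Interferon-stimulated genes were lower too, 19 of 26 with 0 higher and a median of -1.46 at percentile 0.0. RSAD2 was 25.4-fold lower, ISG15 8.51-fold and IFIT3 5.58-fold, while IFIT1 and IFI44 were at least 10.2-fold and 6.58-fold lower. Without probe sets ending in _x_at or _s_at IFI44 had a log2 ratio of -0.99. Macrophage markers were present on both arrays. Of 21 measured, 4 were at least 2-fold lower, HLA-DRA by 3.28-fold, CD74 by 2.63-fold, MS4A7 by 2.41-fold and CD53 by 2.15-fold. The probe set of MS4A7 that differed least had a log2 ratio of -0.57. CSF1R went from 1067 to 12757, a log2 ratio of 3.58. The macrophage list's median was -0.31, at percentile 5.69, and the list stood apart downward with loess centring (-0.43, percentile 0.81).

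Immediate early genes, which are induced within minutes by growth factors and stress, were lower for 18 of 25 members and higher for 0, with a median log2 ratio of -1.63 at percentile 0.0. FOSL1 was 30.7-fold, MYC 29.4-fold, KLF2 14.9-fold, FOSB 10.6-fold and EGR1 9.31-fold lower, whereas FOS and JUND had log2 ratios of -0.38 and -0.12. KLF2 had a log2 ratio of -0.01 without probe sets ending in _x_at or _s_at. Other genes among the lowest were the ephrin EFNB2 at 38.9-fold, the matrix protein THBS1 at 31.7-fold, endothelin 1 (EDN1) at 27.5-fold and EMP1 at 26.2-fold. Stratifin (SFN), an epithelial 14-3-3 protein, went from 28210.3 to 1501, 18.8-fold lower. The growth factor EREG was at least 29.3-fold and the fatty acid transporter SLC27A2 at least 18.6-fold lower. SLC13A3 was at least 15.3-fold lower, but another of its probe sets had a log2 ratio of -0.14. For THBS1 and EMP1 the probe set that differed least had log2 ratios of -0.40 and -1.03.

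Oxidative phosphorylation genes were slightly higher, with a median log2 ratio of 0.44 at percentile 99.52. Of 33 members 6 were at least 2-fold higher, among them NDUFB10 by 3.27-fold, NDUFB5 by 2.66-fold and NDUFB3 by 2.55-fold, and cytochrome c (CYCS) was lower with a log2 ratio of -1.04. The other probe sets of NDUFB10 and CYCS had 0.84 and -0.70. Without probe sets ending in _x_at or _s_at the list no longer stood apart, with a median of 0.32 at percentile 92.64. Cell junction genes were lower as a list, with a median of -0.58 at percentile 0.23, but 4 members were at least 2-fold lower and 4 higher. Occludin (OCLN) and claudin 4 (CLDN4) were 3.29-fold and 3.08-fold lower, and EPCAM, TJP3 and cingulin (CGN) 3.66-fold, 3.07-fold and 2.74-fold higher. TJP3 was short of 2-fold with the floor at the 70th percentile (0.44), and the probe set of OCLN that differed least had -0.33. All 26 measured ribosomal protein genes differed by less than 2-fold, with a median of -0.58 at percentile 0.27. RPS9 had the lowest log2 ratio of these, -0.93, and was 2-fold lower with equal medians of bright probe sets (-1.07) and by the median of its probe sets (-1.18). Equal medians took the ribosomal list's median to -0.73 and loess centring to -0.26.

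Several lists did not stand apart from random lists under the main settings, and the medians of the hypoxia, nutrient transport, unfolded protein, heat shock and keratin lists changed sign between scalings of the arrays. For hypoxia-induced genes the median log2 ratio was -0.04 and the mean 0.13, with PFKP 8.97-fold and ANGPTL4 4.20-fold higher and PFKFB3 7.41-fold and VEGFA 4.14-fold lower. Another probe set of PFKP had a log2 ratio of -0.73. FLT1, the VEGF receptor 1, was 5.38-fold higher by its brightest probe set and is uncertain because another probe set was lower with a log2 ratio of at most -2.53. In the nutrient transport list, with a median of 0.01 and a mean of -0.24, the HDL receptor SCARB1 was 7.95-fold higher and the sulfate transporter SLC13A4 10.9-fold lower, and SLC16A10 and LRP2 were at least 7.23-fold and 6.65-fold lower. SLC16A10 had a log2 ratio of -0.61 without probe sets ending in _x_at or _s_at. The unfolded protein response had a median of -0.03, with 1 of 25 members at least 2-fold higher and 4 lower. CHAC1 was 5.14-fold and SESN2 3.83-fold lower, and SDF2L1 2.35-fold higher. The p53 and apoptosis list had a median of -0.29, with 4 of 22 members at least 2-fold higher and 5 lower. GADD45A was 7.01-fold, PLK3 5.72-fold and AEN 4.34-fold lower, and BCL2 4.65-fold and BAX at least 4.13-fold higher. BAX was short of 2-fold with the floor at the 70th percentile (0.81). By the median of their probe sets PLK3 and BCL2 had log2 ratios of -0.93 and 0.27, short of 2-fold, and by the same measure the p53 list stood apart downward (-0.51, percentile 0.23). The heat shock list had a median of 0.04, with 2 of 16 members at least 2-fold higher and 2 lower. The small heat shock proteins CRYAB and HSPB1 were 9.06-fold and 6.06-fold higher. HSPA6 and CHORDC1 were 2.447-fold and 2.275-fold lower, but short of 2-fold by the median of their probe sets (-0.785 and -0.855). Without probe sets ending in _x_at or _s_at the heat shock list stood apart downward (median -0.52, percentile 1.62). Keratins had a median of 0.05, with KRT19 5.27-fold higher and KRT14 3.42-fold lower. KRT7 was 3.27-fold higher by its brightest probe set and had a log2 ratio of -0.19 by the probe set left after removal of those that may bind related transcripts. Matrix genes had a median of -0.34, with TIMP2 6.67-fold and SPARC 3.42-fold higher and MMP9 3.58-fold and PLAU 3.51-fold lower. The matrix list stood apart downward with the floor at the 35th percentile (-0.47, percentile 2.26) and with no floor (-0.45, percentile 2.42).

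**Figure D3:**
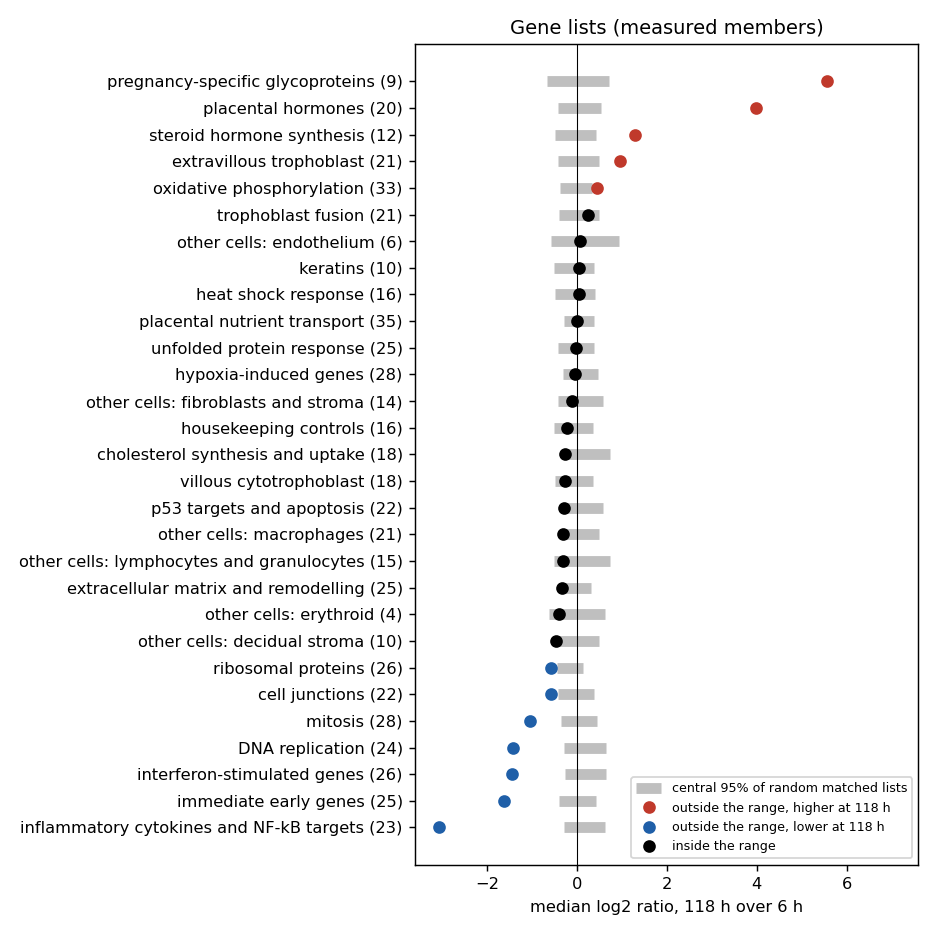
Median log2 ratio (118 h over 6 h, x axis) of the 29 gene lists, with the number of measured members in brackets. Grey bars show the central 95% of medians of 10000 random lists matched on signal, red and blue points lie outside them, and black points inside. Pregnancy-specific glycoproteins are highest at 5.57 and inflammatory genes lowest at -3.07.

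Markers of other cell types were compared as a check on the cultures. The medians of the fibroblast and endothelial lists changed sign between scalings of the arrays. Fibroblast and stromal markers had a median log2 ratio of -0.10 and a mean of 0.23, with POSTN 14.8-fold and MFAP5 3.04-fold higher and vimentin (VIM) 6.13-fold lower. TAGLN was 7.28-fold higher but had a log2 ratio of -0.21 without probe sets ending in _x_at or _s_at. Of 17 endothelial markers 6 were measured, with a median of 0.07. ESAM was at least 26.9-fold and CDH5 2.94-fold higher, while PECAM1 stood at 800.4 and 797.5. Lymphocyte and granulocyte markers had a median of -0.31, with S100A9 4.92-fold and CSF3R 2.22-fold higher, PTPRC 2.35-fold lower and IL7R at least 9.63-fold lower. Erythroid markers had 4 measured members and a median of -0.40, none differing by 2-fold. Decidual stroma had a median of -0.46, with SFRP1 4.71-fold higher and IGFBP1 at least 3.15-fold lower, which was not seen with the floor at the 70th percentile (-0.42). None of these lists stood apart from random lists under the main settings.

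Control probe sets of ACTB, GAPDH and ribosomal RNA bear on the RNA. The ratio of the 3 prime to the 5 prime control probe set of ACTB was 1.05 at 6 h and 1.18 at 118 h, and that of GAPDH was 1.14 and 0.93. The 3 probe sets of 18S ribosomal RNA were lower at 118 h, with a median log2 ratio of -1.36. Their 118 h signals included 135.5 and 124.8, under the floor, which was not applied to control probe sets. The 28S probe sets had a median of -1.67 and disagreed, from -1.94 to 1.16. None of the 16 measured housekeeping genes differed by 2-fold, and their median log2 ratio was -0.21 and turned to 0.11 with loess centring. TBP and SDHA had log2 ratios of 0.67 and 0.93, and POLR2A and TOP1 of -0.94 and -0.79. POLR2A was 2-fold lower with equal medians of bright probe sets (-1.08).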

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

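The test of the spike controls described here was chosen after its result was seen, and the test of array scaling before. The control probe sets, which enter no comparison of genes, included bacterial RNAs of the kind that is added to a sample before cDNA synthesis. The 6 probe sets of dap had a median log2 ratio of -0.62 (118 h over 6 h) and the 6 of lys of -0.94, against -0.07 for the 18 probe sets of the hybridisation controls, which ranged from -0.34 to 0.23. Over the 12 dap and lys probe sets the median was -0.85, with a range from -1.13 to -0.45. The log2 ratios of the spikes thus were not equal. The 3 trp probe sets, which were at about the brightest level of the array (34295 at 6 h), had a median of -0.26. Ribosomal protein genes lay in the same direction, with a median of -0.58.

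Array scaling was weighed first. Equal medians of bright probe sets moved the ribosomal median to -0.73, and quantile normalization and loess centring to -0.40 and -0.26. The highest value over the alternative scalings, -0.26, was short of 0 but above the bound of -0.3 set for excluding this explanation, so a brightness-dependent difference between the arrays stays open. A larger amount of messenger RNA per unit of total RNA at 118 h may also lower every spike. It needs 1 factor for all spikes, and the measured ratios were unequal. The brighter spikes fell less, with median signals at 6 h of 6364 for lys, 19097 for dap and 34295 for trp. A brightness-dependent response could therefore hide 1 factor, so the unequal ratios decide nothing. The pooled value of -0.85 cannot be told apart from uneven addition, because the amounts added are not given. Culture time as a biological explanation stays open and was not tested.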

How the results depend on the processing

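Of 196 named genes 158 kept their side of the 2-fold threshold and their direction under the alternatives that gave them a value, and 24 of 29 lists kept theirs with respect to random lists. Values under all 10 alternatives existed for 128 genes. Without probe sets ending in _x_at or _s_at 57 had none, and with the floor at the 70th percentile 14 had none. Of the 38 genes that changed, the called ones that reversed are given here. The causes of the changes below were not tested unless stated. The rescaling factors were 0.99988 and 0.99989, so the values as deposited test nothing. With no floor and no filter, 3591 genes were higher and 3195 lower (52.9% of calls higher, against 62.9%). With 50 added before log2 the same 19732 genes entered, and 2417 were higher and 1786 lower. Adding 50 also shrinks the ratios of dim genes, and 1941 of 2177 higher and 1152 of 1282 lower genes stayed called. With no floor 2143 and 1270 of them stayed called. These counts do not tell the entry of dim genes from the size of their unfloored ratios. A 3-fold threshold left 879 higher and 518 lower genes, and 391 and 254 genes had at least 2 probe sets that were all 2-fold in 1 direction, both by construction fewer. Across the other alternatives the higher genes numbered 1572 to 2548 and the lower ones 933 to 1838. Equal medians shifted the median log2 ratio from 0.10 to -0.02. Lists that kept their call changed in size too. Over the alternatives the DNA replication median ran from -1.512 to -0.723 and the mitosis median from -1.652 to -0.819. That of interferon-stimulated genes ran from -1.77 to -0.999. Without probe sets ending in _x_at or _s_at, the heat shock median went to -0.519 (percentile 1.62, 10 members) from 0.04, the oxidative phosphorylation median to 0.32 (percentile 92.64), KRT7 to -0.192 and TAGLN to -0.208, and the pregnancy-specific glycoproteins gave no value because fewer than 3 members were left. The p53 list stood apart with the median of a gene's probe sets (-0.507), the matrix list with the floor at the 35th percentile (-0.474) and with no floor (-0.446), and the macrophage list with loess centring (-0.427). With the floor at the 70th percentile the decidual and erythroid lists gave no value, again with fewer than 3 members. No paired analysis was possible because there is 1 array per time. Signals near the floor limit the rest: folds of 376 higher and 256 lower genes are bounds.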

Other observations

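The gene lists in the first 2 paragraphs, and all tests below except those of array scaling and of ribosome biogenesis, were chosen after the data were examined. Ligands of the EGF family were lower at 118 h, except NRG1. Of 4 measured, EREG was at least 29.3-fold, HBEGF at least 11.5-fold and TGFA 2.49-fold lower, and NRG1 stood at 154 and 152. The list's median log2 ratio was -2.42, at percentile 0.0 of random lists. The list had 8 members, so it rests on the 4 measured ones. EREG was already named among the 6 largest bounds lower, so the percentile is no separate evidence. Angiogenic factors and receptors went both ways, with 5 of 13 higher and 5 lower. The list's median was 0.72 and its mean -0.34, at percentile 93.93 for the median. Placental growth factor (PGF) went from 1103 to 14376, a log2 ratio of 3.70 (0.12 by its other probe set), endoglin (ENG) was 5.36-fold, VEGFB 2.24-fold and ANGPT2 at least 4.01-fold higher. EFNB2, THBS1 and EDN1, already among the 12 lowest genes, were 38.9-fold, 31.7-fold and 27.5-fold lower. VEGFA was 4.14-fold and NRP2 2.07-fold lower. The probe set that differed least had a log2 ratio of 0.39 for ANGPT2 and -0.10 for NRP2. For FLT1, 4 of 5 probe sets were higher, with log2 ratios of 1.83 to 2.43, and the other went from 831 to 82.3. Across all genes, probe sets disagreed by 2-fold each way in 138 of the 6251 genes with at least 2 measured, 79 of which were among the higher genes and 19 among the lower ones.

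Imprinted genes did not stand apart, with a median of -0.41 at percentile 6.32. PEG10, GRB10 and MEST were 4.46-fold, 4.09-fold and 3.12-fold lower, ZFAT was 3.71-fold higher, and the cell cycle inhibitor CDKN1C went from 11566 to 22793, a ratio of 1.97. Lysosomal protein genes had a median of 0.30 at percentile 93.84, with MCOLN1 4.09-fold higher and the cholesterol transporter NPC1 3.34-fold lower. Other probe sets of GRB10 and NPC1 had log2 ratios up to 0.11 and 0.13.

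MYC, a transcription factor that activates genes of ribosome assembly, was 29.4-fold lower, by 1 probe set. The hypothesis that ribosome biogenesis genes are lower with it was tested on a list written before its values were seen. Of 25 measured members 11 were lower and 1 higher, with a median log2 ratio of -0.94 at percentile 0 of random lists. NOP58, RRP12 and NOP16 were 3.18-fold, 3.28-fold and 3.21-fold lower, and EMG1 had a log2 ratio of 1.32. The probe set that differed least had -0.38 for RRP12 and -0.48 for NOP16. The result is consistent with the hypothesis, but 2 arrays do not show that MYC is the reason, and this list was not examined under other scalings.

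Inflammatory and interferon-stimulated genes were both lower at 118 h. Array scaling is argued against, since the higher of their medians over the scalings that moved values was -1.49. For the inflammatory genes, loss of macrophages during culture as the whole cause is argued against by the macrophage markers. Their median was -0.31, with a 95% bootstrap interval over members of -0.62 to -0.21. The median and its interval lay above -1.53, a limit derived from the inflammatory list's median of -3.07. The interval treats markers as independent draws and measures no spread between cultures. The interferon list's median of -1.46 itself lay above that limit, so the test does not decide for the interferon genes. The macrophage interval lay above -1.46 too, but no limit was set for that list. CD14 stood at 2010.1 and 1171, C1QC at 2069 and 2398 and LYZ at 9721 and 8992. HLA-DRA went from 11799 to 3598 and CD74 from 14539 to 5524. Of 21 measured macrophage markers 4 were at least 2-fold lower and 1 higher. A partial loss of macrophages stays open, and so does a change of state within trophoblasts or within the macrophages. Such a change of state may also account for the lower immediate early genes. The culture time itself was not tested as a cause.

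Single markers of endothelium (ESAM, CDH5), stroma (POSTN, TAGLN, MFAP5) and macrophages (CSF1R) were higher at 118 h. The tests counted, among all list members with a probe set, those above the floor and at least 2-fold higher, these genes included. Of the endothelial members 2 of 17 were counted (exact 95% interval of the share 1.5% to 36.4%). For fibroblasts it was 3 of 23 (2.8% to 33.6%) and for macrophages 1 of 23 (0.1% to 21.9%). The counts argue against outgrowth of endothelial cells or fibroblasts, or more macrophages, on a scale that lifts most of their markers 2-fold. The intervals treat markers as independent draws and measure no spread between cultures. Rises that start below the floor, as for COL3A1 and COL6A3, can count as less than 2-fold, so a modest outgrowth could be missed. Of the endothelial members 11 lay under the floor on both arrays, among them VWF (73.4 and 37.2), KDR (14.6 and 49.9), CLDN5 (22.9 and 24.7) and PLVAP (75.1 and 69.8), and the 6 measured ones alone decide nothing (median log2 ratio 0.065, bootstrap interval -0.62 to 3.15). A small number of such cells is not excluded, since COL3A1 went from 74.1 to 251.7 and COL6A3 from 20.8 to 148.5, while COL1A1 stood at 656.4 and 798.3, COL1A2 at 227.5 and 200.4 and DCN at 397.1 and 228.4. Expression of these genes by the trophoblasts themselves is a candidate explanation that was not tested.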
